A study of Mus musculus with 26 samples.

How the data were processed

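RNA was sequenced from the livers of Eµ-MYC mice, a transgenic line in which MYC is driven by the immunoglobulin heavy chain enhancer and in which B-lineage lymphomas can arise. The mice had lived for 8 weeks under chronic jet lag lighting (CJL) or under normal lighting of 12:12 light and dark. Libraries were stranded mRNA libraries made from column-purified RNA and sequenced on a DNBSEQ instrument, per the labels. The 26 libraries fell into 4 groups: 8 females under 12:12 lighting, 8 females under jet lag, 6 males under 12:12 lighting (numbers 1 to 6) and 4 males under jet lag (numbers 5 to 8). The shifting schedule, the age of the animals, their state of health and the time of day at which livers were taken are not given in the sources used here.

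The deposited raw table held an expected count of reads per gene name and library, without normalization by the authors. In it 45.82% of cells held 0.015, which stood for 0 and was set to 0, and 1.44% of cells were not whole numbers (tolerance 1e-06), so they were rounded. Its 36930 lines held 36883 gene names, and counts of lines that shared a name were summed. The submitters' notes name STAR, DESeq2 and the mm10 build without versions, and the counting tool, the annotation and the strand setting are not given in the sources used here. The normalized table deposited by the authors held a signal, the rounded count multiplied by 1 constant per library in 99.97% of its cells (relative tolerance 0.001). It was used only to check the raw table. The authors also deposited a DESeq2 table with a mean signal, a log2 fold change of 12:12 over jet lag with its log2 standard error, a score (the Wald statistic), a p-value and an adjusted p-value per gene, which was used only for a side by side count. Gene positions came from a RefSeq annotation of the GRCm38.p6 build, the same assembly as mm10. It matched 29178 of the names by symbol and 1328 by synonym, and 6377 names had no match. Among the names of the normalized signal 22 had turned into spreadsheet dates, so names were taken from the raw table.

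Library totals ran from 45364552 to 50242014 counts. In one library 3 counts, the limit that a count of 0 allows, stood for at most 0.0796 CPM (counts scaled to a common library size), a limit that covers counting error only. No 2 libraries of a group were copies of each other, since the chi-square per degree of freedom between them was at least 31.5.

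Genes were kept when filterByExpr of edgeR 4.0.16 passed them by group with a count minimum of 10, which left 16892. Counts were scaled by TMM, and a negative binomial model was fitted with quasi-likelihood F tests (estimateDisp, glmQLFit with robust estimation, glmQLFTest). Jet lag against 12:12 lighting over both sexes came from an additive model of sex and lighting over all 26 libraries. The comparisons within females, within males, the difference between the sexes in their response (the interaction) and the female to male differences under each lighting came from a model of the 4 group means, also over all 26 libraries. P-values were adjusted over the genes by Benjamini and Hochberg and the threshold was an adjusted p of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Log2 CPM values used a prior count of 2. The adjusted p-values of genes in all parts are from edgeR unless another tool is named.

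The groups, comparisons, tests, gene lists, other settings and the rule for named genes were fixed before the data were examined. For the comparison over both sexes the named genes were the 10 higher and the 10 lower genes with the smallest p among those past the threshold, with a mean of at least 1 CPM and with fold changes of the same sign in females and males. From each list up to 4 members with the smallest p were added. For the female, male and interaction comparisons the rule took the 5 higher and 5 lower genes past the threshold, and for the sex comparisons the 5 higher and 5 lower under 12:12 lighting plus the sex chromosome check genes. Myc was always named, and every member of the clock lists could be named.

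There were 31 gene lists with 515 entries, of which 514 were found in the table. The pathway lists were the clock repressor arm, the clock activator arm, HSF1 and heat shock, cold-inducible RNA-binding proteins, bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARA targets, glucose metabolism, xenobiotic metabolism, acute phase, interferon response, ER stress, p53 targets, MYC and ribosome biogenesis, proliferation, male-biased liver and female-biased liver. The cell type lists were B-lineage, T and NK cell, macrophage and Kupffer cell, neutrophil, erythroid, stellate cell and fibroblast, endothelial cell, cholangiocyte and gallbladder, pancreatic acinar cell and adipocyte. The immediate early and mitochondrial encoded lists served as signs of tissue handling and RNA quality, and the sex chromosome check list served to check the labels. The other 30 lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, adjusted over the 30 lists, again with a correlation estimated from the residuals, and with fry.

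The B-lineage score of a library was the mean log2 CPM of the detected B-lineage genes. A library counted as above the limit when its score exceeded the median of all libraries by more than 3 scaled median absolute deviations. The spread of the clock genes was compared as the ratio of standard deviations (SD) around the group means, jet lag over 12:12, and the B-lineage score as a difference of means. Both used two-sided permutation tests with 100000 resamples of the lighting labels within each sex. The clock index of a library was its mean z-score over the activator arm minus that over the repressor arm. Principal components used the 1000 most variable genes. The spread tests, the list tests and each comparison were tested on simulated data. In counts with the same design 200 genes with a mean of at least 1 CPM were changed, 100 of them 2-fold and 100 4-fold. Of these 89 and 97 were called over both sexes, 72 and 93 in females, 53 and 92 in males and 35 and 78 in the interaction. In the sex comparison 64 and 96 were called under 12:12 lighting and 57 and 92 under jet lag. Unchanged genes gave 5 to 9 false calls per comparison. The simulated genes varied independently, without a sex difference or variation shared through B-lineage RNA, so these shares need not hold for the real libraries.

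The other settings fixed in advance were other scaling factors (DESeq2 size factors, upper quartile), no filter beyond 1 count, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, an adjusted p of 0.1, an absolute log2 fold change above 1, the B-lineage score or 1 surrogate variable (sva 3.50.0) as a covariate, no sex term, a replicate block, single-sex fits, other list tests, other measures of spread, leaving out the libraries above the B-lineage limit, and leaving out each library in turn. Further settings for the list tests, the clock gene spread and the B-lineage level were chosen after seeing the data. Every count was also recomputed in other splits of the same libraries, 100 per comparison with the real one included. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Paralogs with nearly identical transcripts, among them Sult2a1 and Sult2a2, Cyp2a4 and Cyp2a5, Cyp2b9 and Cyp2b13, and the Cyp3a41 and Mup families, can exchange reads, and how the authors assigned such reads is not given in the sources used here. Read sequences were not used here.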

Results

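Liver RNA of 26 Eµ-MYC mice was measured, with 8 females and 6 males kept under 12:12 lighting and 8 females and 4 males kept under chronic jet lag lighting. Each library held between 45364552 and 50242014 counts. Albumin (Alb) was the most abundant transcript in every library and took from 10% to 22.1% of the counts. Expression is given as CPM with its SD over the libraries of a group, and fold changes are log2 values with their SE.

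The first question was how gene expression in the liver differed after 8 weeks of jet lag lighting. Over both sexes, 12 jet lag libraries against 14 libraries under 12:12 lighting, 132 of 16892 genes differed, 75 higher and 57 lower under jet lag, and all 132 had the same sign in females and in males. Among the higher genes were Npas2, which encodes a partner of BMAL1 in the circadian clock, and Insig2, which encodes a protein that retains SREBP in the endoplasmic reticulum. Among the lower genes were the clock gene Per2, Nampt, which encodes the rate-limiting enzyme of NAD salvage, Gys2, which encodes liver glycogen synthase, and Alas1, which encodes the rate-limiting enzyme of heme synthesis. Of the 132 genes, 56 changed by more than 1 on the log2 scale.

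Eps8l2 (chromosome 7, 141338911 to 141363020) had the smallest p and was higher under jet lag by 1.14 (SE 0.16, adjusted p = 0.00141), with 18.0 ± 4.56 CPM in females and 23.4 ± 6.57 CPM in males under 12:12 lighting against 38.1 ± 7.87 and 55.7 ± 23.7 CPM under jet lag. It lay above the 12:12 median of its sex in 11 of 12 jet lag libraries. B230206H07Rik, whose annotated span overlaps that of Eps8l2, rose by 1.14 (SE 0.17), and reads of the overlap cannot be told apart without the counting rule. Insig2 (chromosome 1, 121304353 to 121332662) was higher by 1.21 (SE 0.19, adjusted p = 0.002), at 28.2 ± 5.30 against 55.0 ± 18.1 CPM in females and 30.0 ± 12.8 against 91.9 ± 39.0 CPM in males, in 12 of 12 jet lag libraries. The ubiquitin ligase gene Nedd4l rose by 1.00 (SE 0.15), the threonyl-tRNA synthetase gene Tars by 0.67 (SE 0.11), the Wnt co-receptor gene Lrp5 by 0.58 (SE 0.10) and Clpx, which encodes a subunit of a mitochondrial protease, by 1.43 (SE 0.23). Each of these 4 was higher in 12 of 12 jet lag libraries. Asap2, Rab36 and the cGMP phosphodiesterase gene Pde9a rose by 1.41, 1.06 and 1.11, each in 11 of 12 libraries. The adjusted p of the 10 higher genes named by the rule ran from 0.00141 to 0.00339.

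Nampt (chromosome 12, 32820335 to 32853369) was lower under jet lag, with a fold change of -0.87 (SE 0.15, adjusted p = 0.00339), at 84.0 ± 9.69 against 54.5 ± 15.5 CPM in females and 116 ± 28.2 against 47.7 ± 14.6 CPM in males. Nmrk1, which encodes another enzyme of NAD synthesis, nicotinamide riboside kinase, had a fold change of -0.85 (SE 0.15). Gys2 (chromosome 6, 142422612 to 142473130) had a fold change of -1.09 (SE 0.19, adjusted p = 0.00477), at 323 ± 125 against 152 ± 56.3 CPM in females and 422 ± 119 against 199 ± 15.0 CPM in males. Wee1, which encodes a kinase that restrains CDK1, had a fold change of -1.40 (SE 0.25) and Coq10b, which encodes a coenzyme Q binding protein, one of -1.55 (SE 0.25). Lonrf1 fell by 1.10, the DNA repair gene Dclre1a by 0.77, the ribosome maturation kinase gene Riok2 by 0.45, the mitochondrial adenylate kinase gene Ak4 by 0.81 and LOC102632388, which had no position in the annotation, by 1.92. All 10 of these genes were lower in 12 of 12 jet lag libraries, and their adjusted p ran from 0.0015 to 0.00518. All 20 genes stayed past the threshold in each of the 26 fits that left out 1 library.

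**Figure D1:**
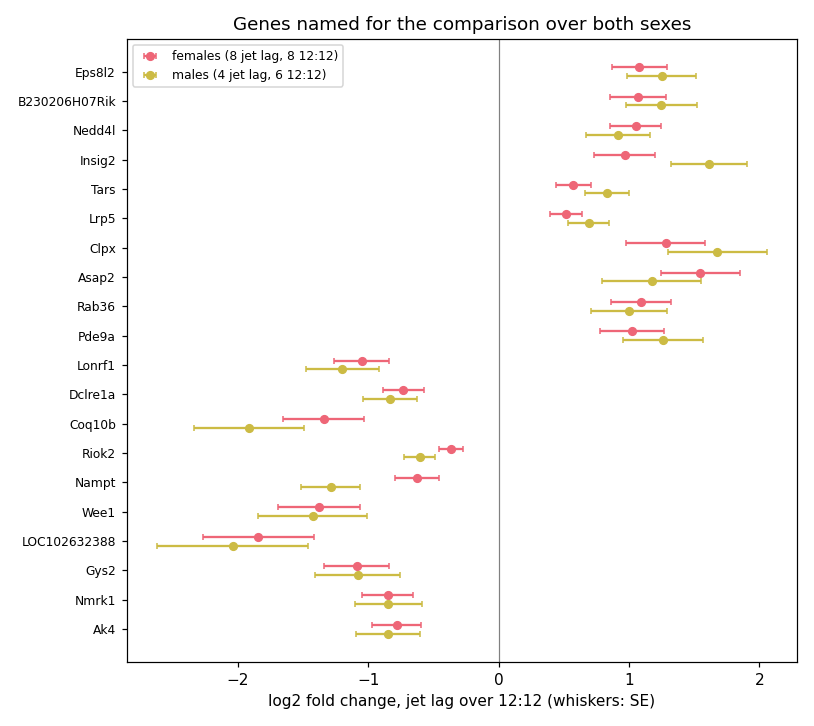
Log2 fold change of jet lag over 12:12 lighting (x axis) for the 10 higher and 10 lower genes named by the rule (y axis), fitted in females (8 against 8 libraries) and in males (4 against 6), with the SE as whiskers. Each gene lies on the same side of 0 in both sexes because the rule required it, for example Insig2 at 0.97 in females and 1.61 in males.

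Among the 132 genes, 67 stayed past the threshold in each of the 26 fits that left out 1 library, and none changed sign. The count itself ran from 70 without female jet lag library 3 to 244 without male jet lag library 8. Without the 8 libraries whose B-lineage score was above the limit the count was 381, of which 115 were among the 132. The authors' table, from DESeq2, called 222 genes, 131 higher and 91 lower under jet lag, including 128 of the 132.

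Of the 13 measured genes of the clock repressor arm, which holds genes driven by BMAL1 of which several repress it, 12 had a negative fold change. Over all genes 4 fell and 9 did not pass. Adjusted over the list alone 12 fell, all but Nr1d1. Usp2 (chromosome 9, 44067021 to 44095627) had a fold change of -1.90 (SE 0.34, adjusted p = 0.00518), from 30.3 ± 7.53 to 9.04 ± 7.84 CPM in females and from 27.4 ± 7.73 to 6.07 ± 3.11 CPM in males. Per2 (chromosome 1, 91415977 to 91459351) had a fold change of -1.38 (SE 0.28, adjusted p = 0.0133), and both genes were lower in 12 of 12 jet lag libraries. The repressor gene Ciart had a fold change of -2.21 (SE 0.51, adjusted p = 0.0347) in 11 of 12 libraries and Tef, which encodes a PAR bZIP factor, one of -1.0 (SE 0.24, adjusted p = 0.049) in 12 of 12. Not past the threshold over all genes were Per1 at -1.23 (adjusted p = 0.0755), Per3 at -1.27 (adjusted p = 0.145), Dbp at -1.28 (adjusted p = 0.373), Bhlhe40 at -0.98, Bhlhe41 at -0.94, Nr1d2 at -0.66, Hlf at -0.57, Cry2 at -0.35 and Nr1d1 at 0.54 (adjusted p = 0.745). The list was lower as a whole (camera, adjusted p = 7.9e-28), with adjusted p = 0.00695 with an estimated correlation and 0.00187 by fry. Ciart stayed past the threshold in 10 and Tef in 6 of the 26 fits without 1 library, with adjusted p of 0.0706 and 0.0887 without male jet lag library 7. Without the libraries above the B-lineage limit Per2 had an adjusted p of 0.0582, Ciart of 0.057 and the list one of 0.0837 with an estimated correlation.

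Of the 7 genes of the clock activator arm, which holds Arntl (the gene of BMAL1), its partners and genes that peak near them, 1 rose and 6 did not pass over all genes, and 4 rose and 1 fell adjusted over the list alone. Npas2 (chromosome 1, 39193702 to 39363240) was higher by 4.30 (SE 0.74, adjusted p = 0.00371) in 12 of 12 jet lag libraries. Its level was near the lower limit of detection, at 0.0795 ± 0.0853 against 1.97 ± 2.89 CPM in females and 0.136 ± 0.216 against 2.03 ± 1.99 CPM in males, so the size of its fold change depends on a few counts. Arntl had 1.65 ± 1.67 against 10.5 ± 10.4 CPM in females and 5.33 ± 9.46 against 17.0 ± 9.01 CPM in males (fold change 2.29, SE 0.58, adjusted p = 0.0636). Leaving out male 12:12 library 3 brought its adjusted p to 0.00104, and leaving out female jet lag library 3 brought it to 0.15 (fold change 1.94). Clock stood at 0.85 (adjusted p = 0.074), Nfil3 at 1.10 (adjusted p = 0.102), Cry1 at -0.20 and Rora at -0.14. The list was higher as a whole (camera, adjusted p = 0.00847), which was lost with adjusted p = 0.66 with an estimated correlation. It also missed the threshold without male jet lag library 6 (adjusted p = 0.142) and without female jet lag library 1 (adjusted p = 0.0581).

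**Figure D2:**
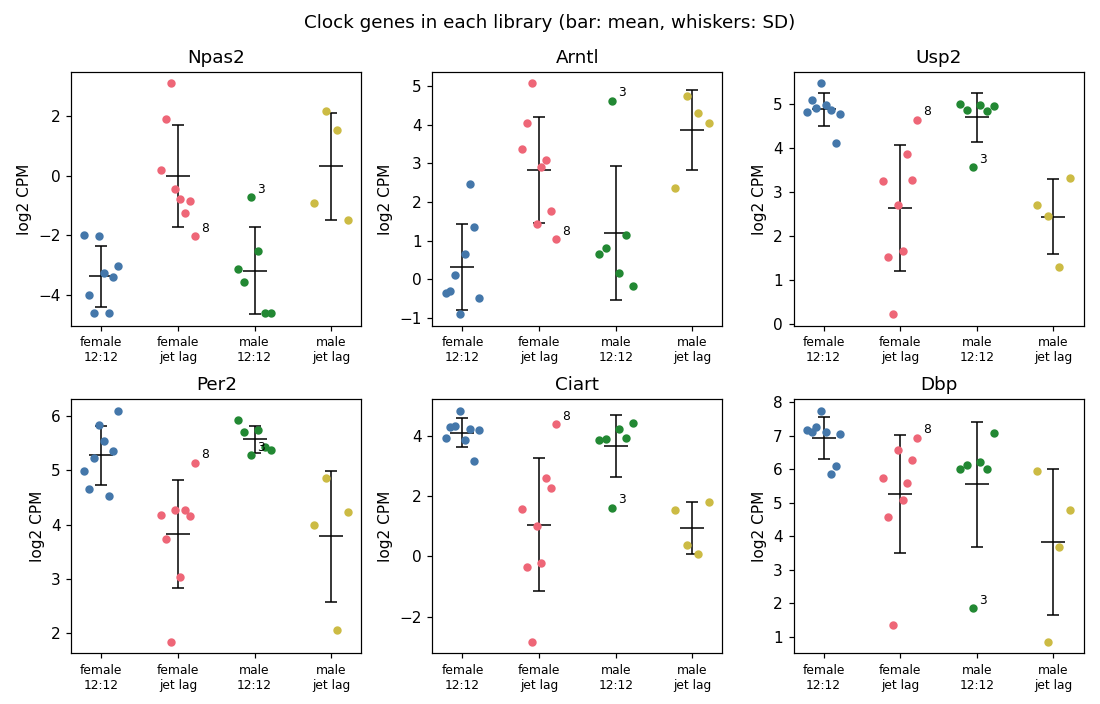
Log2 CPM (y axis) of 2 clock genes with a higher mean (Npas2, Arntl) and 4 with a lower mean (Usp2, Per2, Ciart, Dbp) under jet lag, 1 point per library, by sex and lighting (x axis), with the group mean as a bar and the SD as whiskers. The numbers 3 and 8 mark male 12:12 library 3 and female jet lag library 8, and Arntl lay at 4.62 in male 12:12 library 3 against -0.17 to 1.15 in the other 5 males under 12:12 lighting.

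Of 23 genes of xenobiotic metabolism, 3 fell and 20 did not pass over all genes, and 4 fell adjusted over the list alone. Alas1 (chromosome 9, 106233455 to 106247954) had a fold change of -1.47 (SE 0.31, adjusted p = 0.0167), from 1078 ± 421 to 398 ± 187 CPM in females and from 1312 ± 554 to 457 ± 449 CPM in males. Por, which encodes the electron donor of microsomal cytochromes P450, had a fold change of -0.80 (SE 0.15, adjusted p = 0.00883) in 12 of 12 libraries, and Cyp2a5, which encodes coumarin hydroxylase and can exchange reads with Cyp2a4, one of -1.16 (SE 0.23, adjusted p = 0.0105) in 11 of 12. The list was lower as a whole (camera, adjusted p = 2.47e-05), which was lost with adjusted p = 0.66 with an estimated correlation. Without the libraries above the B-lineage limit Alas1 had an adjusted p of 0.0539 and the list one of 0.106. Of 18 genes of glucose metabolism 1 rose, 1 fell and 16 did not pass over all genes, and 3 rose and 3 fell adjusted over the list alone. Gys2 was the gene that fell, and Ppp1r3c, which encodes a subunit that brings phosphatase to glycogen, rose by 1.13 (SE 0.27, adjusted p = 0.0473). Ppp1r3c stayed past the threshold in 8 of 26 fits without 1 library, with an adjusted p of 0.101 without female jet lag library 2. As a set the glucose list did not shift one way (camera, adjusted p = 0.442), while fry for changes in either direction gave an adjusted p of 0.000827.

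No member of the other 26 tested lists passed over all genes, and camera passed none of them. Adjusted over the list alone, 1 member rose in the fatty acid oxidation and PPARA list, the pyruvate dehydrogenase kinase gene Pdk4 (fold change 1.75, SE 0.48, adjusted p = 0.0959 over all genes), and 1 in the p53 target list, the apoptosis gene Bbc3 (0.80, SE 0.21, adjusted p = 0.0643). The median fold change was -0.02 for HSF1 and heat shock, 0.02 for cold-inducible RNA-binding proteins, -0.06 for bile acid synthesis and transport, -0.01 for cholesterol synthesis, -0.10 for fatty acid synthesis, 0.04 for fatty acid oxidation and PPARA targets and 0.09 for acute phase. It was -0.04 for interferon response, 0.05 for ER stress, 0.17 for p53 targets, -0.02 for MYC and ribosome biogenesis, 0.22 for proliferation, 0.01 for male-biased and 0.20 for female-biased liver genes. Among cell type lists it was 0.01 for B-lineage, 0.00 for T and NK cell, -0.01 for macrophage and Kupffer cell, -0.18 for erythroid, 0.25 for stellate cell and fibroblast, 0.09 for endothelial cell, 0.18 for cholangiocyte and gallbladder, -0.07 for pancreatic acinar cell and 0.06 for adipocyte genes. The immediate early list stood at -0.08 and the mitochondrial encoded list at 0.05. For 9 lists not past the threshold the median, mean and test differed in sign (cold-inducible RNA-binding, bile acid, fatty acid synthesis, glucose, male-biased liver, B-lineage, T and NK cell, macrophage and adipocyte). Neutrophil genes had the largest median, 1.10, with 11 of 11 positive and none past (camera, adjusted p = 0.305). S100a8, for example, had 7.31 ± 16.9 against 19.3 ± 48.2 CPM in females. Without the libraries above the B-lineage limit the neutrophil median was -0.17 over the 7 genes that stayed measurable.

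Within females, 8 libraries against 8, no gene passed by edgeR, with 772 genes at an unadjusted p under 0.05, and DESeq2 called 55 and limma-voom 124. Other edgeR fits called 14 genes with female libraries only, 31 with the B-lineage covariate and 20 with the replicate block. The clock repressor arm was lower in females (median -1.16, camera adjusted p = 1.4e-20, adjusted p = 0.0331 with an estimated correlation), with 8 of 13 genes lower adjusted over the list alone. The activator arm was higher (median 1.09, camera adjusted p = 0.000707, adjusted p = 0.349 with an estimated correlation), with 4 of 7 higher and 1 lower adjusted over the list alone. Camera also passed lower xenobiotic metabolism (adjusted p = 4.74e-05) and MYC and ribosome biogenesis (adjusted p = 0.0072) and higher acute phase (adjusted p = 0.025), stellate cell (adjusted p = 0.00451) and endothelial cell genes (adjusted p = 0.000707). With an estimated correlation these 5 had adjusted p of 0.425, 0.997, 0.997, 0.349 and 0.425. Proliferation genes (median -0.549, 0 of 24 positive) and B-lineage genes (median -0.618, 2 of 18 positive) also lay lower in females, neither list past the threshold. The count rose from 0 to 13 without female jet lag library 8, 11 without male 12:12 library 3, 6 without male jet lag library 8 and 2 without male 12:12 library 5.

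Within males, 4 libraries against 6, Nampt and Slc16a12 fell and 1630 genes had an unadjusted p under 0.05. Slc16a12, which encodes a creatine transporter, had a fold change of -1.35 (SE 0.23, adjusted p = 0.0476), from 68.6 ± 14.1 to 26.9 ± 6.46 CPM. Nampt had a fold change of -1.29 (SE 0.23, adjusted p = 0.0476), from 116 ± 28.2 to 47.7 ± 14.6 CPM, and all 4 jet lag males lay below the 12:12 median for both genes. The clock repressor arm was lower (median -1.27, camera adjusted p = 1.23e-12, adjusted p = 0.262 with an estimated correlation), with 9 of 13 genes lower adjusted over the list alone. DESeq2 called 94 genes and limma-voom 124 in males. In edgeR, DESeq2 size factors gave 0, male libraries only gave 0 and leaving out the libraries above the B-lineage limit gave 219. Without 1 library, 18 of the 26 fits gave 0. The others included 106 without male jet lag library 8, 45 without male 12:12 library 3, 8 without male jet lag library 6, 4 without female 12:12 library 6 and 1 without female 12:12 library 8.

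The next question was whether females and males responded differently. No gene passed the interaction test by edgeR, with 902 at an unadjusted p under 0.05 and a smallest adjusted p of 0.682, and DESeq2 and limma-voom called 0 and 0. For Nampt and Slc16a12 the interaction gave an adjusted p of 0.814 each, so the calls in males are not shown to be absent in females. Camera passed 4 lists for the interaction. Relative to males, interferon response (adjusted p = 0.0113), acute phase (adjusted p = 0.0272) and endothelial cell genes (adjusted p = 0.0124) had higher fold changes in females, and MYC and ribosome biogenesis genes lower ones (adjusted p = 0.0158). No member of these 4 lists passed, and each had an adjusted p of 1 with an estimated correlation. Proliferation genes (median -1.955, 0 of 24 positive) and B-lineage genes (median -1.803, 2 of 18 positive) also had lower fold changes in females, neither list past the threshold.

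The spread of the clock genes between animals was compared because animals under shifting light can differ in phase. Per1 varied more between the jet lag libraries, with an SD of 1.30 against 0.25 under 12:12 lighting (ratio 5.28, permutation p = 0.00121, adjusted p = 0.023), and so did Nfil3, with an SD of 1.23 against 0.34 (ratio 3.56, permutation p = 0.0023, adjusted p = 0.023). The other 18 clock genes did not pass. Of the 20 genes 17 had a ratio above 1, and the median ratio was 1.49 (permutation p = 0.128, 12 against 14 libraries). By median absolute deviation in place of the SD it was 1.93 (permutation p = 0.0478), and without the libraries above the B-lineage limit, a setting chosen after seeing the data, 2.99 (permutation p = 0.00242). Without male 12:12 library 3 the median ratio was 1.75 (permutation p = 0.0336), and 5 genes passed. Other omissions weakened the result: without male jet lag library 6 the median ratio was 1.355 (permutation p = 0.285), and without library 7 1.391 (permutation p = 0.278). The calls of Per1 and Nfil3 were both lost without male jet lag library 8, where 0 genes passed. Only 1 gene passed without male jet lag library 7, female jet lag library 2 or female jet lag library 3.

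B-lineage genes were measured because lymphoma can develop in this line. The B-lineage score did not differ detectably between jet lag and 12:12 lighting (difference 0.072, within-group SD 1.54, permutation p = 0.914), with means of 1.19 ± 1.55 and 1.17 ± 1.26 in females and 0.957 ± 1.47 and 1.12 ± 2.14 in males under 12:12 lighting and jet lag. The score was above the limit of 1.59 in 8 of 26 libraries: 2 females and 2 males under 12:12 lighting, 3 females and 1 male under jet lag. These 8 scored from 1.74 to 4.30 and the other 18 at most 0.73. In the same 8 libraries Cd79a, a component of the B cell receptor, ranged from 13.3 to 133 CPM and the proliferation gene Mki67 from 18.6 to 280 CPM. Myc had a fold change of 0.01 (SE 0.81, adjusted p = 0.999) between lightings, with 17.5 to 271 CPM in the 8 libraries, and 24.1 and 22.3 CPM in male 12:12 libraries 2 and 6, whose scores were -0.27 and 0.07. The first principal component of all libraries held 54.4% of the variance and correlated with the B-lineage score across libraries (r = 0.969).

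**Figure D3:**
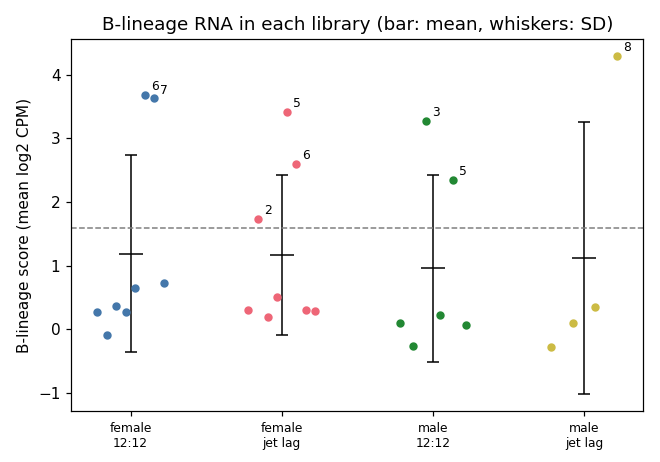
B-lineage score (y axis, mean log2 CPM of B-lineage genes) of each library by sex and lighting (x axis), with the group mean as a bar and the SD as whiskers. The dashed line is the limit of 1.59, and the replicate numbers mark the 8 libraries above it, at least 1 in each group.

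Female and male livers were compared under each lighting to check the labels and to give the scale of a known difference. Xist, the RNA of X inactivation, had 745 ± 117 and 766 ± 166 CPM in females under 12:12 lighting and jet lag and 0.195 ± 0.0819 and 0.24 ± 0.253 CPM in males. The Y-linked genes Ddx3y (62.2 ± 4.18 and 40.7 ± 15.3 CPM), Eif2s3y (50.5 ± 4.88 and 54.1 ± 6.99 CPM), Kdm5d (22.2 ± 2.44 and 20.3 ± 3.66 CPM) and Uty (18.2 ± 1.18 and 14.9 ± 1.99 CPM) were measured in males. In the 16 females Eif2s3y had no count, which allows up to 0.0639 CPM in a library, and Uty, Kdm5d and Ddx3y had at most 0.02, 0.02 and 0.0578 CPM. Under 12:12 lighting 622 genes differed by sex, 340 higher and 282 lower in females. Under jet lag 324 differed, 147 higher and 177 lower, and 212 genes passed under both lightings, all with the same sign. With upper quartile scaling the 324 genes called under jet lag were 209 higher and 115 lower, so the balance of directions depends on the scaling. Among genes higher in females the sulfotransferase genes Sult2a2 and Sult2a1 had 327 ± 85.0 and 336 ± 116 CPM in females under 12:12 lighting against 0.0173 ± 0.0274 and 0.0109 ± 0.0267 CPM in males. Hao2 had 37.3 ± 13.8 against 0.0231 ± 0.0375 CPM and Cyp3a41a 1178 ± 739 against 16.2 ± 2.71 CPM. Nox4 was lower in females, at 7.32 ± 1.92 against 36.1 ± 7.36 CPM (fold change -2.30, SE 0.20, adjusted p = 1.47e-08).

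Of 26 female-biased liver genes 21 were higher in females under 12:12 lighting (24 adjusted over the list alone) and 14 under jet lag (21 adjusted over the list alone). Of 24 male-biased genes 19 were lower in females under 12:12 lighting (23 adjusted over the list alone) and 18 under jet lag (23 adjusted over the list alone). The count of 324 under jet lag moved to 967 without male jet lag library 8, to 194 without male jet lag library 6 and to 212 without male jet lag library 7. The count of 622 moved to 346 without male 12:12 library 1 and to 352 without male 12:12 library 4. Without the libraries above the B-lineage limit 1357 genes differed under 12:12 lighting and 1902 under jet lag, so the order of the counts depends on those libraries.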

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

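Chosen only after the result was seen were the test of B-lineage RNA behind the 132 genes, the swap tests and the B-lineage test of male 12:12 library 3, and both tests of Cyp2b9. Dixon's criterion was applied to 277 groups of 4 to 8 values, over the library totals, the B-lineage score, the clock index and 71 genes. It found 44 single values far from the rest of their group, where chance gives about 1 in 20. Mup20, Cyp2b9, Cyp2b13, Cyp4a12a, Cd79a and Mki67 were among the 71 although the naming rule did not pick them. The 44 are therefore not a fair count against chance. Another 19 groups of values with a median count under 10 were not tested. Male 12:12 library 3 held 20 of the 44, male jet lag library 8 held 8 and female 12:12 library 6 held 6.

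In male 12:12 library 3 the clock index was 1.90 (others -1.11 to -0.19). On the log2 CPM scale this library had Arntl at 4.62 (others -0.17 to 1.15), Clock at 4.94 (3.44 to 3.82) and Lrp5 at 6.80 (6.11 to 6.29), all above the other 5 males under 12:12 lighting. Below them lay Per3 at 3.78, Nr1d2 at 3.88, Dbp at 1.85, Tef at 4.89, Ciart at 1.62, Usp2 at 3.57, Coq10b at 2.80, Wee1 at 3.17, LOC102632388 at 1.15, Gys2 at 7.68, Cyp2a5 at 9.82 and Nox4 at 4.49. The same library had Elovl3 at -2.04 (others 3.77 to 5.22), Mup20 at 3.78 (8.95 to 10.74), Cyp4a12a at 2.73 (7.93 to 9.57) and Cyp2b13 at 5.52 (-3.12 to -1.12).

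Male jet lag library 8 had a B-lineage score of 4.30 (others -0.28 to 0.35), with Cd79a at 7.06 and Mki67 at 8.13 log2 CPM. It also had Mup20 at 2.93 (others 10.62 to 10.83), Elovl3 at -0.25 (7.01 to 8.23), Cyp4a12a at 1.21 (8.57 to 9.79), Pde9a at 3.02 (4.86 to 5.19) and Por at 9.32 (8.11 to 8.24). In female 12:12 library 6 the neutrophil genes S100a8 and S100a9 lay at 5.62 and 6.06 log2 CPM (others at most 1.29 and 1.89), Acox2 at 8.11, Gys2 at 6.77, Tef at 5.10 and Rora at 2.29. Female jet lag library 6 had Mup20 at 0.97, Hsd3b7 at 7.30 and Elovl5 at 6.12. Female 12:12 library 8 had Nedd4l at 3.77 and Riok2 at 5.11, female jet lag library 3 had Rab36 at 3.65 and Dbp at 1.35, and male 12:12 library 1 had Bbc3 at 0.87. Male 12:12 library 6 had the smallest total of its group, 45.36 M counts (others 47.91 to 49.26 M). Male jet lag library 7 had the Y-linked gene Ddx3y at 4.18 (others 5.47 to 5.68).

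Between the sexes, camera gave a different response to jet lag for acute phase (adjusted p = 0.0272), interferon response (adjusted p = 0.0113), MYC and ribosome biogenesis (adjusted p = 0.0158) and endothelial cell genes (adjusted p = 0.0124), each with adjusted p = 1 with an estimated correlation. Like the MYC list, proliferation genes (median -1.955) and B-lineage genes (median -1.803) had lower fold changes in females, neither list past the threshold.

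The first pattern is the 132 genes called between jet lag and 12:12 lighting over both sexes. One candidate cause is B-lineage RNA that differed between the lightings. All 132 stayed past the threshold with the B-lineage score as a covariate. That score hardly differed between the lightings (difference 0.072, within-group SD 1.54), so the covariate could remove few calls and does not decide the question. Without the 8 libraries above the B-lineage limit 115 of the 132 passed, which argues against B-lineage RNA as the whole cause for those 115. A shifted phase of the liver clock is a candidate explanation: 92.9% of the called genes outside the clock lists (118 of 127) followed the clock index within the groups in the direction of their lighting difference (one-sided permutation p = 0.0216, median correlation across libraries 0.49). What stays open is the hour at which each liver was taken, which is not given in the sources used here: a difference in hour between the lighting groups and a shifted clock predict the same values. The calls may therefore reflect phase rather than a lasting change in level.

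The second pattern is that the clock genes of male 12:12 library 3 (index 1.90) and female jet lag library 8 (index -1.04) lay among the other lighting group. A swap within males is argued against, as every jet lag male had an index at least 0.454 outside the range of the other 12:12 males, whose SD was 0.345. B-lineage RNA is argued against for male 12:12 library 3, whose index was 2.33 above the highest of the 3 other 12:12 libraries above the B-lineage limit, against a within-group SD of 0.375. A swap within females cannot be told apart from chance, with a gap of 0.066 and an SD of 1.21. A single wrong label also stays open: 73 of 127 called genes outside the clock lists in male 12:12 library 3 and 74 of 127 in female jet lag library 8 were nearer to the other lighting, and a different phase of one animal could give the same.

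The third pattern is Cyp2b9 at 442 and 310 CPM and Mup20 at 13.7 and 7.60 CPM in male 12:12 library 3 and male jet lag library 8, where the 7 males under the B-lineage limit had from 1.52 to 43.0 CPM of Cyp2b9 and from 1018 to 1818 CPM of Mup20. Female liver RNA or a wrong sex label is argued against, since Xist was at most 0.000678 of the level that the Cyp2b9 share would bring. Dilution by B-lineage RNA is argued against, since Cyp2b9 was at least 7.2-fold above the highest of those 7 males. The shift was not limited to Cyp2b9 and Mup20. The mean log2 CPM of the male-biased liver list was 3.69 and 3.51 in the pair, against 7.13 to 7.88 in the other males. For the female-biased liver list it was 4.75 and 5.14, against 1.70 to 2.44. Male 12:12 library 5, also above the limit, had 25.3 CPM of Cyp2b9 and 494 CPM of Mup20, and Cyp3a41a stayed at 15.9 and 12.1 CPM in the pair. Reads shared with Cyp2b13 (45.9 and 68.9 CPM) stay open for Cyp2b9 only, and no biological explanation was tested, since the design gives no group for it.

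Other splits of the same libraries tested whether chance could give the counts. For the 132 genes 3 of 100 splits were as large, the real one included, so chance seldom gave as many but is not excluded. The highest other split gave 1775 genes and another 1429, many times the real count, which points to a structure of the samples. In these splits the mean B-lineage score differed between the label groups by 1.82 and -1.59, against 0.072 in the real split. Another split with a difference of 1.73 gave 0 genes, so the score difference alone does not set the count. For the males chance cannot be excluded (2 genes, 7 of 100 splits as large, highest other 1442). In the females (0 genes, 100 of 100, highest other 5) and the interaction (0 genes, 100 of 100, highest other 3361) no gene was called, so every split gives at least as many and the splits decide nothing about chance. A single split gave both 1442 and 3361 genes, at a B-lineage score difference of 0.466, and also points to a structure of the samples. For the number of gene lists past the threshold chance cannot be excluded (3 lists, 98 of 100 splits as large, highest other 20). The p of the clock repressor arm alone was reached in 1 of 100 splits, the real one, that of the activator arm in 8 and that of xenobiotic metabolism in 15. For the sex difference under 12:12 lighting chance can be excluded (622 genes, 1 of 100 splits as large, highest other 0). Under jet lag chance seldom gave as many but is not excluded (324 genes, 3 of 100, highest other 1505). There the split with 1505 genes again points to a structure of the samples. That split had a B-lineage score difference of -2.18 and a split with 961 genes one of -2.25, against 0.056 in the real split. A further split at -2.21 gave 0 genes.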

How the results depend on the processing

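The leave-one-out rounds of the clock gene spread and the B-lineage level, the list tests without the libraries above the B-lineage limit or with an estimated correlation under a covariate, and the spread without those libraries were chosen after seeing the data; all others were planned. The cause was not tested for any change below. For the comparison over both sexes (132 genes) DESeq2 gave 274, limma-voom 565, the B-lineage covariate 295, 1 surrogate variable 318, leaving out the libraries above the B-lineage limit 381, an adjusted p of 0.1 208 and an absolute fold change above 1 56. Other scaling, other filters, no sex term and the replicate block stayed within 1.5 times, with 111 genes under the block, 73 of them among the 132. Replicate numbers do not pair the libraries, as 1 of 10 same-number pairs correlated best with its own number. Without 1 library the count ran from 70 to 244: female 12:12 library 4 gave 85 and 8 gave 73, female jet lag 2 gave 87 and 3 gave 70, male 12:12 2, 3, 4 and 5 gave 76, 214, 87 and 82, and male jet lag 5 and 8 gave 82 and 244. In females (0) DESeq2 gave 55, limma-voom 124, the B-lineage covariate 31, the surrogate variable 37, no libraries above the limit 13, the replicate block 20, female libraries only 14 and an adjusted p of 0.1 1 gene, and leaving out 1 library gave 0 to 13. In males (2) the same settings gave 94, 124, 34, 55 and 219, the replicate block 0, male libraries only 0 and DESeq2 size factors 0, and leaving out 1 library gave 0 to 106. The interaction (0) gave 2 with the surrogate variable and 0 in all 26 fits without 1 library. For sex under 12:12 lighting (622) DESeq2 gave 977, limma-voom 2975, the B-lineage covariate 1261, the surrogate variable 1393, no libraries above the limit 1357, an adjusted p of 0.1 1020, a fold change above 1 334, and leaving out 1 library 346 to 848. Under jet lag (324) the same settings gave 650, 909, 883, 940, 1902, 619, 213 and 194 to 967, and upper quartile scaling put 64.5% rather than 45.4% of the called genes higher in females. Of the gene lists (3 past) an estimated correlation left 1, fry 1, an estimated correlation with the B-lineage covariate 1 and without the libraries above the limit 0. Without 1 library 2 to 6 passed, with 6 without female 12:12 library 6, 5 without male jet lag library 7 and 5 without male jet lag library 8. The spread ratio (1.49) was 1.93 by median absolute deviation (permutation p = 0.0478), 2.99 without the libraries above the limit (permutation p = 0.00242) and 1.36 to 1.75 without 1 library. The B-lineage difference (0.072) was -0.462 to 0.335 without 1 library, lowest without male jet lag library 8. None of the 150 named genes changed direction past the threshold in any of these settings, and scaling moved the median of all genes by under 0.1.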

Other observations

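Without the 8 libraries above the B-lineage limit, a setting that also left 10 libraries under 12:12 lighting and 8 under jet lag, more genes of the clock lists passed over all genes. Arntl rose by 3.61 (SE 0.52, adjusted p = 0.00138) and Nfil3 by 1.29 (SE 0.28, adjusted p = 0.018), while Per1 had a fold change of -1.44 (adjusted p = 0.0491), Hlf of -0.55 (adjusted p = 0.019) and Bhlhe40 of -1.05 (adjusted p = 0.0446). In that setting 5 of 13 repressor arm genes fell and 3 of 7 activator arm genes rose. Genes of bile acid synthesis then passed as well, Acox2 by 0.57 (SE 0.09, adjusted p = 0.00151) and Hsd3b7 by 0.61 (adjusted p = 0.0183), where 2 of 18 genes of that list rose. The median of the bile acid list was -0.01, with 4 genes higher and 3 lower adjusted over the list alone. Elovl5, which encodes a fatty acid elongase, rose by 0.63 (SE 0.14, adjusted p = 0.0217). Over all 26 libraries these 3 metabolic genes had adjusted p from 0.367 to 0.498. Without the 8 libraries 2 of 13 p53 targets and 1 of 24 male-biased liver genes also rose. In the cholesterol synthesis, MYC and ribosome biogenesis, female-biased liver and B-lineage lists 1 gene each fell.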
